A study of Mus musculus with 2 samples.

How the data were processed

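Gene expression was measured in total RNA of pancreatic islets, labelled with biotin and hybridised to Affymetrix mouse expression arrays, as 1 array for each of 2 samples. Per the labels, the samples are male mice aged 6 weeks, and the groups were taken from the genotype given for each sample. The labels do not say how many mice contributed to a sample. The deposited values are log2 expression values per probe set. Per the submitters' processing notes, the authors made them with RMA in Affymetrix Expression Console, with versions not given in the sources used here. RMA corrects the background, normalizes the arrays to a common distribution and summarises the probes of a probe set. The sorted values of the 2 columns differed by at most 0.10, as such a normalization leaves them. Whether other arrays were normalized together with these 2 is not given. RMA values carry no detection call and compress differences at the bottom and at the top of the scale. The number of arrays limits the precision: with 1 per group there is no estimate of error.

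Probe sets were named through the platform's annotation table, and symbols were updated through Entrez Gene identifiers to those of the GRCm38.p6 gene table. Of 45101 probe sets 64 were array controls, 34945 had 1 gene symbol, 932 had several and 9160 had none in that table. Of those with 1 symbol 34741 matched by identifier. Probe sets without a single symbol were left out of gene results. No coordinates are given, since the array files name no genome build. Each gene took the probe set with the highest mean of both arrays. A gene was kept when at least 1 of its values reached the floor of 5.76, the median of all probe set values. The difference was the transgenic minus the control value, and the size rule was a log2 difference of 1 (2-fold).

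The study design, 31 gene lists, the size rule and the rule for named genes were fixed before the data were examined. The lists came from general knowledge and included markers of acinar, ductal, endothelial, stellate, myeloid, lymphoid, glial, fat and blood cells. The percentile of a list's median was taken among 10000 random lists of the same size drawn from 20 bins of mean expression, for lists with at least 3 kept members. It describes these 2 arrays and is not a p-value. The procedure was tested on simulated data made from the real differences of 12143 genes shuffled within expression bins. Each simulated list was set against 1000 random lists. Of 200 unshifted lists of 20 genes 5% fell outside the central 95%. With the list shifted by 0.1, 0.2 and 0.4, 24.5%, 67.5% and 100% fell outside it on the higher side. Shuffling removes links between genes regulated together, so the 5% need not hold for lists of such genes. Named genes were the 10 furthest in each direction without predicted or RIKEN models, 12 genes fixed by name of which 10 had a value, up to 4 kept members of each list that was apart, in its direction, and up to 2 of every other list. Further lists of enterocyte, hepatocyte, heat shock and cholesterol and lipid synthesis genes were added after seeing the data. The list values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

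Alternatives tried were the mean over probe sets, leaving out probe sets of the _s, _x and _a classes, no floor or a floor at the 75th percentile, subtraction of a lowess trend (statsmodels 0.14.6, span 0.3), a second quantile normalization, a 1.5-fold rule, and for lists unmatched random lists, the mean, and leaving out the furthest member or members of other lists. The planned search of 3' UTRs for sites matching positions 2 to 8 of the microRNAs was not run, because no transcript sequence was used here.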

Results

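Pancreatic islets of 2 kinds of male mice aged 6 weeks were profiled on expression arrays. One sample came from transgenic mice overexpressing the microRNAs miR-141 and miR-200c, and the other from control mice of the C57BL/6 strain. The labels give islets as the tissue and beta cells as the source, and do not say how many mice contributed. miR-141 and miR-200c belong to the miR-200 family, small RNAs that repress messenger RNAs carrying matching sites. The series title places the question in beta cell survival in type 2 diabetes. There was 1 array per genotype (n = 1), so no value below has a replicate error, no p-value was computed, and no difference has a replicate check. Every difference is the transgenic minus the control log2 RMA value of these 2 arrays, and the words higher and lower describe these arrays only. A gene called higher or lower by the size rule differed at least 2-fold. A list of genes was called apart when its median lay outside the central 95% of the medians of 10000 random lists matched on expression.

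The arrays held 45101 probe sets each, with a median log2 value of 5.76 on both. Pearson's r between them was 0.988 across probe sets, which are not independent replicates. Of 18193 genes measured by a probe set with a single gene symbol, 12143 reached the floor of 5.76 on at least 1 array. The central 95% of their differences ran from -0.63 to 1.0, with a median of 0.029. Probe sets of the same gene gave differences that were a median of 0.19 apart. Signals of the array's control RNAs differed between the samples. All 24 poly-A spike control probe sets were higher on the transgenic array, by a median of 1.51, and all 18 hybridisation control probe sets by a median of 0.40. The signal of poly-A spikes depends on the amounts of spike and of sample RNA, which are not given in the sources used here, so equal RNA input was not established. The 3 probe sets for 18S rRNA were lower, with a median difference of -0.83. The 3' minus 5' difference, a sign of RNA integrity, was 1.21 for Actb in the transgenic and 1.09 in the control sample, and 0.55 and 0.68 for Gapdh. The Y-linked genes Eif2s3y and Uty had values above the floor on both arrays (8.18 and 8.87, and 7.67 and 7.91, transgenic first), and Xist was below it on both. The 3 kept sex-linked genes had a median difference of -0.25 (percentile 7.13). Nnt, which carries a deletion in one C57BL/6 substrain, read 9.38 and 9.56. No probe set was annotated to a miR-200 family microRNA, so the overexpression itself was not checked here.

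The comparison of transgenic with control islets asked which messenger RNAs differ when miR-141 and miR-200c are overexpressed. At the 2-fold rule, 305 genes were higher and 62 were lower in the transgenic sample. With a floor at the 75th percentile of all values, 168 and 39 of these remained, a 1.5-fold rule gave 939 and 381, and with probe sets averaged per gene 217 were higher and 38 lower. The gene furthest higher was Aass, an enzyme of lysine breakdown, at 9.47 against 4.05, or 42.7-fold. Fabp2 and Fabp1, the intestinal and liver fatty acid binding proteins, were 28.4-fold and 19.8-fold higher. F13a1, which encodes the A subunit of coagulation factor XIII, had values of 11.36 in the transgenic and 6.81 in the control sample, 23.6-fold higher. Aldh1a3, a retinaldehyde dehydrogenase used as a marker of beta cell dedifferentiation, was 13.8-fold higher, and its other probe sets at the floor gave log2 differences of 0.71 and 1.20. Ddias, a suppressor of apoptosis after DNA damage, was 11.2-fold higher. Cldn2, a tight junction protein, and Slc22a2, an organic cation transporter, were each 8.42-fold higher. Dcx, a microtubule protein of young neurons, was 7.42-fold higher, and Sv2c, a synaptic vesicle protein, 7.08-fold. The control values of Aass, Fabp2, Fabp1, Aldh1a3, Ddias, Cldn2, Slc22a2 and Sv2c lay below the floor, so the background of the array limits these folds and their order. The same holds for Pmaip1, Tph2, Tnfrsf11b and Cdh19, named further on.

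The gene furthest lower was Glycam1, a ligand of L-selectin, at 5.74 in the transgenic against 8.64 in the control sample, 7.48-fold lower. Ctrc, the digestive protease chymotrypsin C, was 4.70-fold lower, and Negr1, a neural adhesion protein, 4.59-fold. Tmem255a was 3.75-fold lower, with its 2 other probe sets at -2.03 and -1.97. Pde1c, a cyclic nucleotide phosphodiesterase, was 3.42-fold lower. Hspa1a, an inducible heat shock protein, was 3.23-fold lower, although its probe set can share signal with the near-identical Hspa1b. Slc6a19, a neutral amino acid transporter, was 3.18-fold lower, the transcriptional cofactor Eya1 3.12-fold, the small GTPase Rit2 2.85-fold and Emid1 2.79-fold. The transgenic values of Glycam1, Negr1, Pde1c and Rit2 lay below the floor, so the background limits these folds and their order. Where a gene past the 2-fold rule had other probe sets at the floor, 105 of 114 of these had the same sign for higher genes and 35 of 37 for lower genes. Over all kept genes the share was 66.4%. Probe sets of a gene read the same RNA and are not replicates.

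**Figure D1:**
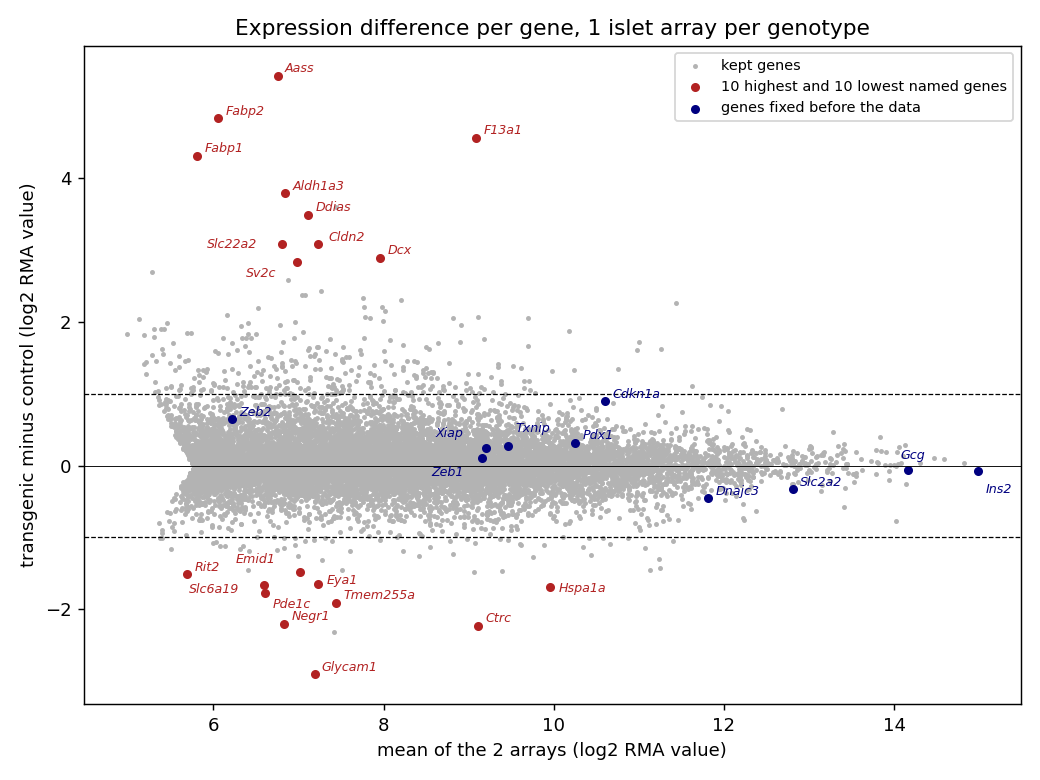
Difference between the transgenic and the control array (vertical axis, log2) against the mean of both (horizontal axis, log2 RMA value), 1 grey point per kept gene (12143 genes), with dashed lines at 2-fold. Red points are the 10 named genes furthest higher, from Sv2c to Aass at 5.42, and the 10 furthest lower, down to Glycam1 at -2.90. Blue points are the genes fixed by name in advance, all within 2-fold.

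The genes that mark beta cells and the other endocrine cells did not stand apart as lists. None of the 22 measured beta cell identity genes passed the 2-fold rule in either direction, and their median difference was -0.017, at percentile 29.9 of matched random lists. Ins2, an insulin gene, read 14.95 in the transgenic and 15.02 in the control sample, near the top of the scale, where arrays compress differences. Pdx1, a transcription factor of beta cells, had a log2 difference of 0.32, the glucose transporter gene Slc2a2 -0.33, the potassium channel subunit gene Abcc8 0.49 and Ucn3, a peptide of mature beta cells, -0.81. Of the non-beta endocrine genes, none of 10 passed the rule (median 0.062, percentile 67.7). The 5 left without members above 13 had a median of 0.28 (percentile 92.1), also not apart. Gcg, the glucagon gene, stood at -0.058, Ghrl, the ghrelin gene, at 0.65 and Rbp4 at 0.30. The 23 granule and exocytosis genes had a median of 0.018 (percentile 56.25), with Syt4, a synaptotagmin, at -0.73 and Cplx2, a complexin, at -0.54. The other 2 probe sets of Cplx2 had the opposite sign. No value is given for Ins1 or Mafa, which had no probe set with that single symbol in the annotation used.

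Genes normally kept low in beta cells, or raised when their identity is lost, were apart on the higher side. Of 16 kept members 14 had a positive difference (median 0.28, percentile 98.6), but only Aldh1a3 passed the 2-fold rule. Igfbp4, which binds insulin-like growth factors, followed at 0.92, with 1 of its 5 other probe sets of opposite sign. Rest, a repressor of neuronal genes, stood at 0.76 and Oat, a mitochondrial aminotransferase, at 0.75. Without Aldh1a3 the percentile was 96.65, inside the central range. Markers of macrophages (median 0.78) and stellate cells (0.39) were also higher, and cells other than beta cells express several members, among them Igfbp4 and Rest.

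Targets of the tumour suppressor p53 were higher as a list. The median of its 32 kept members was 0.34, above all 10000 random lists, and 25 members had a positive difference. Phlda3, an inhibitor of Akt, was 4.42-fold higher, Ckap2 4.02-fold, Ccng1 (cyclin G1) 3.08-fold and Pmaip1, the pro-apoptotic Noxa, 3.04-fold. Polk, a DNA polymerase, passed the 2-fold rule at 1.16, and Tigar was past it on the lower side at -1.01. Polk and Tigar were named after their values were seen. Markers of macrophages (median 0.78, 19 of 20 positive) and stellate cells (0.39) were higher in the same sample. Cdkn1a, the cell cycle inhibitor p21, had a difference of 0.89 and its other probe set 1.14. The 18 pro-apoptotic genes were not apart (median 0.18, percentile 93.6). Pmaip1 alone among them passed the rule, and Bbc3, which encodes Puma, stood at 0.80. The 14 anti-apoptotic genes had a median of 0.24 (percentile 99.8) with none past the rule. Birc5 (survivin) stood at 0.75, Bcl2l2 at 0.65, Tmbim6 at 0.55 and Bcl2 at 0.50. The 3 other probe sets of Bcl2l2 and the other one of Bcl2 had the opposite sign, and with probe sets averaged per gene the list's percentile was 59.89, and 86.97 without the members that other lists hold.

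Cell cycle genes had the highest median of the 29 lists fixed in advance that had a percentile. All 26 kept members were higher in the transgenic sample, 12 of them at least 2-fold and none 2-fold lower, and the median of 0.91 lay above all 10000 random lists. Tpx2, a spindle factor, was 2.93-fold higher, Mcm5, a subunit of the replicative helicase, 2.78-fold, Top2a, a topoisomerase of dividing cells, 2.61-fold and Mki67, the proliferation marker Ki-67, 2.56-fold. Of the 3 other probe sets of Tpx2, 2 had the opposite sign. Markers of macrophages and of stellate cells were higher in the same sample, with medians of 0.78 and 0.39.

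Genes of the unfolded protein response, which serves protein folding in the endoplasmic reticulum, were lower as a list. Of 28 kept members 22 had a negative difference, and the median of -0.16 was at percentile 0.03. Creld2, a chaperone of the endoplasmic reticulum, was 2.21-fold lower and Ddit3, the stress transcription factor Chop, 2.01-fold. Sel1l, of the degradation machinery, stood at -0.76 and the chaperone cofactor Sdf2l1 at -0.62. Dnajc3, a co-chaperone that is also a known miR-200 target, had a difference of -0.46, and its 4 other probe sets ran from -0.49 to -0.24. No member was 2-fold higher.

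The known targets of the miR-200 family, listed from general knowledge, were not apart. None of 25 kept members passed the 2-fold rule and 7 were on the lower side (median 0.10, percentile 87.8). Other cells of the islet sample contribute to these values, and Flt1 and Kdr are also on the endothelial list. Since macrophage and stellate markers were higher (medians 0.78 and 0.39), lower target levels within beta cells were not excluded. Zeb1, a repressor of epithelial genes and a standard target, stood at 0.10, with its other probe sets at 0.18 and 0.50, and the related Zeb2 at 0.64. Xiap, a caspase inhibitor, had a difference of 0.25, while its other probe sets ran from -0.35 to 0.06. Cfl2, a cofilin, stood at -0.81 and the neurotrophin receptor gene Ntrk2 at 0.67. For Ntrk2, 1 of 2 other probe sets had the opposite sign. Epithelial junction genes, which Zeb1 and Zeb2 repress, were not apart either (23 members, median 0.033, percentile 60.2). Patj, a polarity protein, was 2.52-fold higher, and Ap1m2 stood at 0.46. The 7 neighbours of the miR-200c and miR-141 locus had a median of -0.13 (percentile 11.3), with Eno2 at -0.86 and Atn1 at -0.37. Atn1 was below the floor in the transgenic sample, so the background limits its difference.

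**Figure D2:**
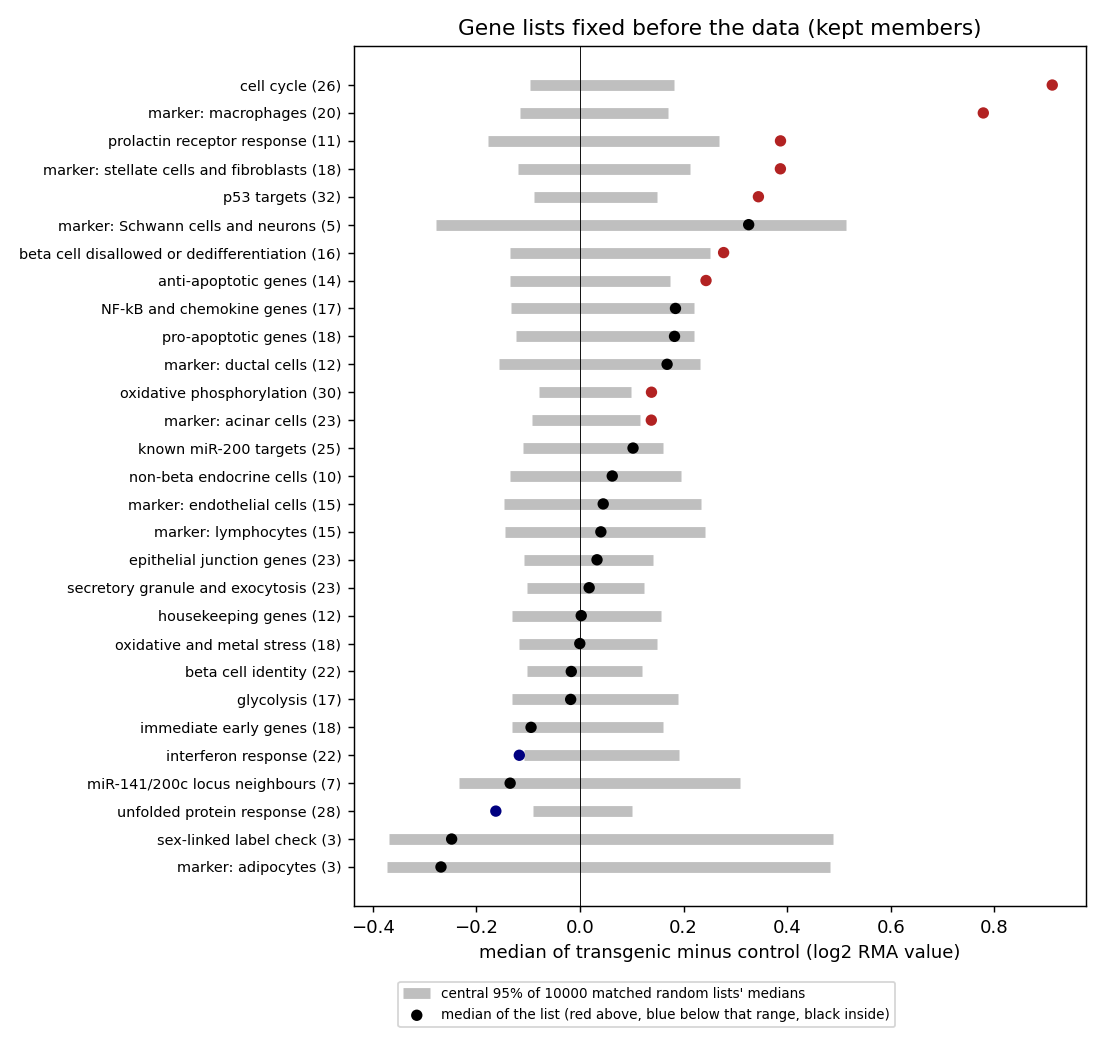
Median difference between the transgenic and the control array (horizontal axis, log2) of each of 29 gene lists fixed in advance, with the number of kept members in brackets. Grey bars are the central 95% of 10000 expression-matched random lists. The 9 red medians lie above that range, the highest being the cell cycle list at 0.91, and the 2 blue medians below it.

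Among markers of other cell types that an islet preparation can hold, those of macrophages differed furthest. Of 20 kept macrophage markers 19 had a positive difference and 3 were at least 2-fold higher, and the median of 0.78 lay above all 10000 random lists. Mpeg1 (perforin-2) was 2.37-fold higher. The complement genes C1qb and C1qc had log2 differences of 1.15 and 1.14, and the integrin gene Itgax one of 0.96. Markers of stellate cells and fibroblasts had a median of 0.39 over 18 members (percentile 99.97), of which 14 were positive and 2 passed the rule. Col1a2, a collagen gene, was 2.42-fold higher and Postn (periostin) 2.08-fold, while the pericyte gene Rgs5 stood at 0.95 and Col3a1 at 0.89. Acinar markers had a median of 0.14 over 23 members (percentile 99.375) with no member 2-fold higher and Ctrc past the rule on the lower side. Pla2g1b stood at 0.78, Spink1 at 0.33, Pnliprp2 at 0.30 and Sycn at 0.27. This call ended when random lists were not matched on expression (percentile 91.325), when the mean was used (71.46), or without members above 13, near the top of the scale (85.275, chosen after seeing the data).

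Markers of endothelial cells (15 members, median 0.045, percentile 55.7) and of lymphocytes (15 members, median 0.040, percentile 52.745) were not apart. Pecam1 stood at 0.88 and Erg at -0.61 among the former, and Cd2 at 0.63 and Cd3d at -0.48 among the latter. The transgenic value of Erg lay below the floor, so the background limits its difference. Ductal markers had a median of 0.17 (12 members, percentile 91.8), with Prom1 2.15-fold higher and Bicc1 at 0.49. The 5 kept Schwann cell and neuron markers had a median of 0.33 (percentile 89.9), with Cdh19 3.09-fold higher and Erbb3 at 0.87. The 3 kept adipocyte markers had a median of -0.27 (percentile 5.72), with Lpl at -0.86 and Fabp4 at 0.38. Of the red blood cell markers only Bpgm reached the floor, at 0.66.

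The remaining lists covered metabolism, stress and signalling. Nuclear genes of oxidative phosphorylation were apart on the higher side with none past 2-fold (25 of 30 positive, median 0.14, percentile 99.85), with Ndufa4 at 0.76, Atp5o at 0.46, Uqcrc1 at 0.33 and Ndufa5 at 0.30. Without the probe sets that can match several transcripts the percentile was 92.79, and 94.81 without matching on expression. Glycolysis genes were not apart (17 members, median -0.018, percentile 28.4), with Eno2 at -0.86 and Aldoc at -0.76. Oxidative and metal stress genes had a median of -0.00031 (18 members, percentile 41.3), with Gpx2 at -0.79 and the metallothionein gene Mt1 at -0.77. Txnip, a regulator of thioredoxin, stood at 0.27. Immediate early genes had a median of -0.094 (18 members, percentile 7.40), with Fos at -0.60 and Ccn1 at 0.86, where 1 of 2 other probe sets of Ccn1 had the opposite sign. Genes of the interferon response were apart on the lower side (22 members, 12 negative and 10 positive, median -0.12, percentile 1.78). Ifit1 stood at -0.66, Igtp at -0.64, Oasl2 at -0.50 and Irf9 at -0.50, and Usp18, named after its value was seen, passed the 2-fold rule on the higher side at 1.05. That call ended with no floor (percentile 6.085), with probe sets averaged (8.42) and with the mean (3.44). The NF-kB and chemokine genes were not apart (17 members, median 0.18, percentile 94.3), with Cxcl10 2.03-fold higher and Vcam1 at 0.79, where 1 of 2 other probe sets of Vcam1 had the opposite sign.

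Genes listed for the response of beta cells to prolactin or growth hormone were apart on the higher side (11 members, median 0.39, percentile 99.6). In the same sample, macrophage and stellate markers were also higher, with medians of 0.78 and 0.39. Its members were not assigned to a cell type. The furthest members of the prolactin list were Matn2 at 4.15-fold, Tph2, a tryptophan hydroxylase, at 3.72-fold and Tnfrsf11b (osteoprotegerin) at 3.43-fold, followed by Ivd at 0.45. With the stricter floor the percentile was 97.465, inside the central range. Cish, a direct response gene of this pathway, stood at -0.11, and Tph1 was below the floor on both arrays. Men1, which prolactin lowers in islets, was among the members, at -0.34. Cish, Tph1 and Men1 were named after their values were seen. Housekeeping genes had a median of 0.0025 (12 members, percentile 45.9), with Gusb at 0.38 and Pgk1 at -0.32. Of the 29 lists with a percentile, 11 were apart, 9 higher and 2 lower. By chance 1.45 would be expected if the genes within a list differed independently, which genes regulated together do not.

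**Figure D3:**
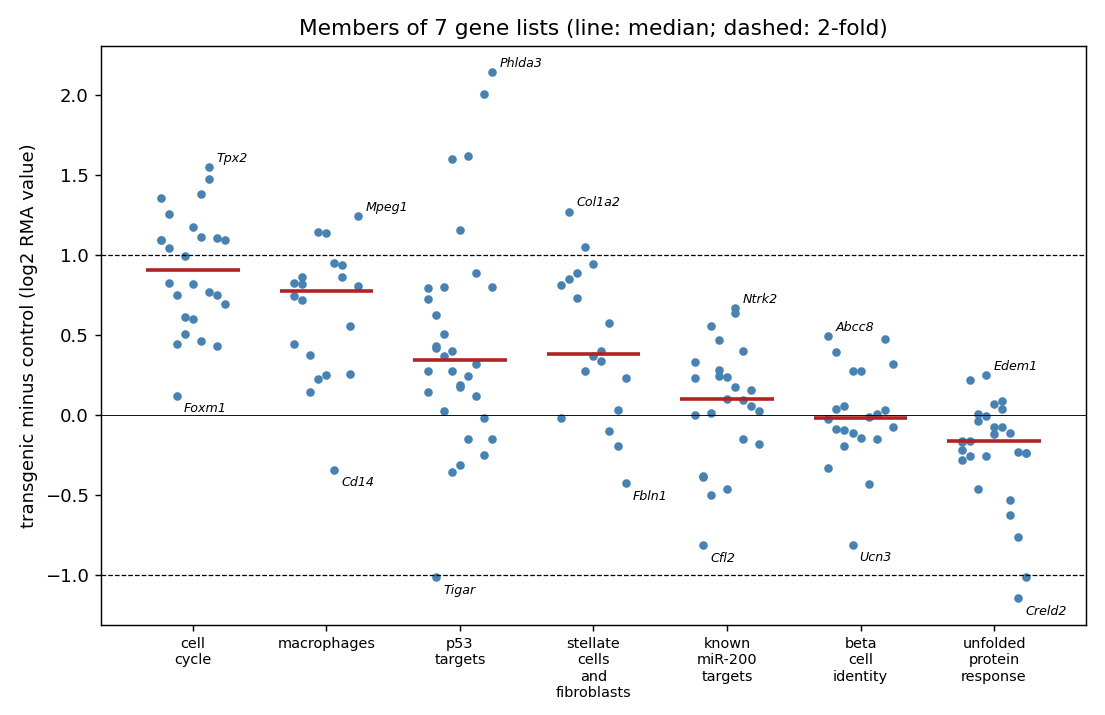
Difference between the transgenic and the control array (vertical axis, log2) of each kept member of 7 gene lists, 1 blue point per gene, with the list's median as a red line and dashed lines at 2-fold. All cell cycle genes lie above 0, the 25 known miR-200 targets lie within 2-fold around a median of 0.10, and the unfolded protein response genes centre on -0.16.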

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

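With 1 array per genotype no sample could be compared with others of its group, so the results below come only from probe sets that the gene comparison left out. Probe sets without a single gene symbol included 42 that were at least 2-fold higher and 19 at least 2-fold lower in the transgenic sample. The probe set 1422411_s_at had a log2 difference of 5.65, from 2.46 in the control to 8.11 in the transgenic sample, and 1449846_at one of 4.16, from 4.24 to 8.40. Both control values lie below the floor of 5.76, so the background limits these differences. Among probe sets with no symbol, furthest lower were 1419568_at at -2.31 (7.48 in the transgenic and 9.79 in the control sample) and 1457124_at at -1.95, where the transgenic value of 5.42 is below the floor. None of these probe sets is named in the annotation used. The poly-A spike controls, RNAs added before labelling, were higher on the transgenic array by a median of 1.51, and the hybridisation controls, added afterwards, by 0.40. The amounts of spike and of sample RNA are not given in the sources used here, so a difference in RNA input was not excluded.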

How the results depend on the processing

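None of the 29 lists fixed in advance changed its call under the lowess trend or the second quantile normalization, and no named gene past the 2-fold rule changed sign (0 of 238 recomputed values). Of those values 9 came under 2-fold. Ccn1, within 2-fold, went to -0.22 without _s, _x and _a probe sets. The counts of 305 higher and 62 lower genes became 168 and 39 with the stricter floor, all among the original genes, and 939 and 381 at 1.5-fold. Averaging probe sets gave 217 higher genes, 206 of them shared, and 38 lower, 34 shared. Higher genes made up 83.1% of both directions and 78.6% to 85.1% under the alternatives that kept 2-fold. Calls of cell cycle, p53 target, macrophage, stellate and unfolded protein response lists held under every alternative run, including p53 targets without Ckap2, Psrc1 and Ccnd1 (chosen after seeing the data). Calls that ended, as percentiles, were: dedifferentiation without Aldh1a3, 96.65; anti-apoptotic genes with probe sets averaged, 59.89, and without members of other lists, 86.97; oxidative phosphorylation without _s, _x and _a probe sets, 92.79, and unmatched, 94.81; interferon response with probe sets averaged, 8.42, with no floor, 6.085, and with the mean, 3.44; prolactin response with the stricter floor, 97.465; acinar markers unmatched, 91.325, with the mean, 71.46, and without members above 13 (chosen after seeing the data), 85.275. Calls gained were oxidative and metal stress with probe sets averaged, 1.88; with the stricter floor NF-kB genes, 99.57, and ductal markers, 99.24; with the mean locus neighbours, 2.41, and sex-linked genes, 1.62; Schwann markers without _s, _x and _a probe sets, 97.90. Lists left with fewer than 3 members gave no percentile. Of the lists added after seeing the data, only the enterocyte list changed its call, with the stricter floor (93.97, 4 members left). The cause was not tested. The planned 3' UTR site search, its alternatives and any replicate left out were not run. Signal over background limits genes near the floor.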

Other observations

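Genes of cholesterol and lipid synthesis, a list written only after Scd2 and Fdps had been seen among the lower genes and without these, were lower in the transgenic sample. Of 21 kept members 20 had a negative difference and none passed the 2-fold rule. The median was -0.47, below all 10000 random lists. Stard4, a sterol carrier, stood at -0.87, the fatty acid elongase gene Elovl6 at -0.86, the sterol sensor gene Insig1 at -0.80 and Hmgcs1, which makes the precursor of mevalonate, at -0.75. Scd1 was the exception at 0.32. Genes of the heat shock response other than Hspa1a, Hspa1b and Dnajb1 had a median of -0.10 over 16 members (percentile 5.81).

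The tests below of macrophage and stellate markers, of secretory cells and of handling stress were chosen after all or part of the values they use had been seen, and how the tests of gut tissue, liver tissue, macrophage spread, intensity trend and secretory cells were read was settled after their values were known. Intervals are over genes, which are not replicates.

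Genes known from the intestine stood among those furthest higher (Fabp2, Fabp1 and Cldn2). Slc6a19, a transporter also known from the intestine, was among the 10 furthest lower, at -1.67. Liver tissue in an amount that raises hepatocyte genes as a set is argued against by a median of -0.020 (interval -0.33 to 0.17) over 22 of them. Of these 16, Alb included, were below the floor on both arrays, so a small share of liver cells was not excluded. Apoa1 (1.38) and Apoa2 (1.02) were 2-fold higher, and the 6 at the floor had a median of 0.29 (percentile 90.9). Gut tissue stays open: the median of 26 other enterocyte genes was 0.47 (95% interval 0.0063 to 0.79), above 0 but below the bound of 1 set in advance, which took no account of a small share of gut cells. Of these 12 were below the floor on both arrays. At least 2-fold higher were 4, among them Mttp at 1.58 and Krt20 at 1.33, the latter below the floor on both arrays. The 14 at the floor had a median of 0.71, above all 10000 random lists (interval -0.31 to 1.08), with 10 positive and 4 negative differences. Rbp2, Apoa4, Slc5a1 and Cdhr2 reached the floor only in the transgenic sample. An effect of the genotype within islet cells was not tested and may remain.

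Markers of macrophages and stellate cells were higher. A lower share of endocrine cells would raise every other cell type alike, but the macrophage median exceeded the pooled median of 30 endothelial and lymphocyte markers by 0.74 (interval 0.37 to 0.88). For stellate markers that gap was 0.35, with an interval also above 0 (0.095 to 0.79). It was smaller than the spread of single stellate markers (quartiles 0.085 and 0.84), so the explanation was left open for them. A higher share of macrophages and higher expression per macrophage cannot be told apart. The interquartile range of the 20 macrophage markers, 0.54, was at percentile 95.8 of matched lists. Arrays compress differences at the bottom and top of the scale, so a change in share need not move all markers equally. This spread therefore cannot decide. Genotype and any difference between the islet preparations, or in the strain background of the mice, coincide in this design.

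Genes of the unfolded protein response were lower. An intensity trend is argued against as the whole cause, since the list was at percentile 0.03 among lists matched on expression, and lowess, which adds little to that matching, left it at 0.05 with a median of -0.18. For fewer secretory cells, the median of 45 beta cell and granule genes was -0.0083 (interval -0.09 to 0.12). That interval lies above the -0.16 of the response genes, the outcome set to count against this explanation. But the interval of the response median itself, -0.25 to -0.07, overlaps it, although overlap is not a test of the gap. Single beta cell and granule genes spread widely (interquartile range 0.33). Some, such as Ins2 at 14.95 and 15.02, read near the top of the scale, where arrays compress differences. Fewer secretory cells therefore cannot be told apart from other explanations. A general stress difference from islet handling stays open. Heat shock and immediate early genes as 1 list of 34 were at percentile 1.70, the outcome set to count for it. Alone, the heat shock genes were at percentile 5.81 and the immediate early genes at 7.40, neither apart. The pooling was chosen after values had been seen, and Atf3 is also a response gene, so the pooled list cannot decide. An effect of the genotype on this response is a further open hypothesis and was not tested.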
